A study of Danio rerio with 4 samples.

How the data were processed

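RNA was extracted with a TRIzol-type reagent, per the labels' protocols, and libraries were made with a Vazyme kit and sequenced on an MGISEQ-2000. The labels give whole embryos at 48 hpf, 2 wild type and 2 tet2/3 double knockout, with replicate numbers 1 and 2 in each genotype and no clutch or day. The submitters' processing notes list STAR 2.7.10a, RSEM 1.3.1 and DESeq2 1.32.0 and the builds GRCz11 and danRer11, without roles. STAR aligns reads and RSEM estimates abundances. The annotation release, read filters and strand setting are not given in the sources used here.

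The deposited values are gene tables of 32057 Ensembl gene identifiers per library. The expected counts were deposited by the authors as RSEM-style estimates that share ambiguous reads among genes, per the file headers, so genes with near-identical copies, overlapping genes and antisense partners are uncertain. The TPM values were computed by the authors, scaled for gene length and library total, per the file headers, and keep no depth. The FPKM values deposited by the authors were not used in any test, and the deposited length columns entered only checks of gene length. Gene names came from a table of identifiers and symbols that named 28988 identifiers. Many symbols are written as the human orthologue and 5966 identifiers share one, so identifiers stand beside shared symbols. No genome was used, so coordinates and GC content were not analysed here.

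Expected counts were rounded to whole numbers. Genes were kept by the edgeR function filterByExpr with its defaults (minimum count 10, minimum total 15) and the groups, which left 20239. The test was the two-sided quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 with TMM normalization, genotype as the only term and Benjamini-Hochberg adjustment at 0.05. The residual degrees of freedom were 2 per gene, with 3.42 from the prior. The SE of a log2 fold change is its size divided by the square root of F. CPM values use TMM library sizes. Fold changes against a group without counts are bounds against 3 counts over the group, and genes with 1 to 3 counts in a group have an exact 95% interval of the count ratio. Both cover counting error only, since reads without molecular identifiers are not independent molecules. Depth ran from 8123036 to 30009099 counts per library, so low wild-type levels rest on fewer reads than equal knockout levels.

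The 42 gene lists, the tests, the rule for named genes and the other settings to try were fixed before the data were examined. List names were matched to symbols directly or, where no symbol matched, without the copy letter: 893 of 1278 names matched directly, 299 without the letter and 86 did not match. Some genes are in more than 1 list, so the lists are not separate evidence. The NOTCH1 genes are in Neural progenitor and Notch pathway. BMP SMADs and target genes shares msx1a and msx2b with Pharyngeal arch patterning and HEY1 with Notch pathway. Lists with 5 or more kept members were tested with camera at a preset correlation of 0.01, adjusted over 41 lists. Of 27 lists called, none held with an estimated correlation, where the smallest adjusted p was 0.271, and 26 were also called in the same direction by fry. Fry does not compare a list with other genes. Counts of members past the threshold are given over all genes and adjusted over the list alone. Where a list had 0 edgeR calls in a direction (Photoreceptor, Neuron, Melanophore and Mitochondrially encoded genes up, Proliferation and Xanthophore down), DESeq2 and limma also had 0, and members at unadjusted p under 0.05 were 1 in Neuron and 0 in the others.

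The named genes are tet1, tet2 and tet3, then the 12 genes per direction with the largest absolute log2 fold change among those past the threshold, with mean CPM of at least 2, both knockout libraries beyond both wild-type libraries and no clone or placeholder name, and up to 4 members per list with the lowest p. Some of these genes are not reported here. The hsp70 genes and the other genes with the symbols RRM2, GREM1, SOX8, LIM2 and BMP2 were chosen after their values were seen. So were the GDF10, gdf3, BMP1 and COL2A1 genes, TFAP2A, TFAP2E, SOX10, crestin and the genes named after SP1 in Bone and osteoblast.

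The other settings were RLE size factors, DESeq2 1.42.0, no filter beyond a total above 0, mean CPM of at least 2, unrounded expected counts, edgeR with legacy=FALSE or robust=TRUE, limma 3.58.1 on log2(TPM + 1) for genes with mean TPM of at least 1, the replicate number as a block, each library left out, and for lists an estimated correlation and fry. Fold changes on log2(TPM + 1) understate changes of low genes. With the data seen, thinning to 8123022 counts per library (the total of the shallowest after rounding), offsets that remove each library's trend against gene length (lowess span 0.3) and omission of the heat-shock list were added.

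The steps were tested on simulated counts for 20239 genes with the real library sizes and 200 changed genes. In this simulated comparison of knockout against wild type, edgeR recovered 30% of the 100 genes changed 2-fold and 83% of the 100 changed 4-fold, with 9 false calls among 122. DESeq2 recovered 40% and 79%, limma 29% and 80%, and the fit with length offsets 30% and 82%. The simulation gave both genotypes the same spread per gene. In the data the genotypes differed in biological coefficient of variation (21.9% in wild type, 4.37% in the knockout). It also changed 200 genes, against 9554 called in the data, so these rates need not hold for the real comparison.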

Results

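The series measured polyA RNA from whole zebrafish (Danio rerio) embryos at 48 hours post fertilization (hpf) by RNA sequencing. It holds 2 wild-type libraries and 2 libraries of tet2/3 double knockout embryos. TET2 and TET3 are dioxygenases that oxidize 5-methylcytosine in DNA, and BMP ligands signal through receptor serine/threonine kinases to SMAD proteins. The title of the series names a TET-BMP axis and CFM, so the comparison asks which transcripts differ between the genotypes, with BMP and craniofacial genes as the genes of interest. Total expected counts were 11022200 and 8123036 in wild type replicates 1 and 2. They were 29340807 and 30009099 in knockout replicates 1 and 2, so depth followed genotype. Levels are given as CPM (counts scaled to the TMM-adjusted library total), mean ± SD over n = 2 libraries, and fold changes are knockout over wild type.

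The targeted transcripts were present in every library. The tet3 transcript stood at 380.2 and 559 CPM in the wild-type libraries and at 404 and 416 CPM in the knockout libraries (log2 fold change -0.20 ± 0.19 (SE), adjusted p = 0.433 by edgeR). TET2 stood at 151 and 209.5 CPM in wild type and at 179 and 175 CPM in the knockout (log2 fold change -0.02 ± 0.17 (SE), adjusted p = 0.923). TET1, the third family member, stood at 9.14 and 22.05 CPM in wild type and at 31.6 and 41.2 CPM in the knockout (log2 fold change 1.24 ± 0.40 (SE), adjusted p = 0.0515). It passed as higher with RLE (adjusted p = 0.0443), DESeq2 (0.00242), no filter (0.0423), legacy=FALSE (0.0439), length offsets (0.0256) and without the heat-shock list (0.0453). TET1 did not pass at mean CPM of at least 2, with unrounded counts, robust=TRUE or limma on TPM, or after thinning. Its log2 fold change was 0.74 without wild type replicate 1, 1.996 without wild type replicate 2 and 1.42 without knockout replicate 1. A gene total does not show which part of a transcript is mutated, and mutant mRNA can persist, so these levels check neither the lesion nor the loss of protein. The sign of TET2 turned with RLE, DESeq2, no filter, TPM, length offsets and without knockout replicate 2 (log2 fold changes from 2.22e-04 to 0.04698). Without wild type replicate 1 the log2 fold changes of tet3 and TET2 were -0.43 and -0.22. Without wild type replicate 2 they were 0.11 and 0.24. A fit with 1 wild-type library takes its spread from the knockout pair alone, so its p-values do not measure wild-type variation and are not given here.

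Cone opsin and other photoreceptor transcripts were among the largest decreases in the knockout, and RRM2, LIN28A and SALL4 were among the largest increases. The neuritin-like gene nrn1lb, the photoreceptor matrix gene impg2b (ENSDARG00000100288) and jac1 had no count in either knockout library, which made them at least 112-fold, 111-fold and 107-fold lower than the wild-type mean against a floor of 3 counts over the group. From wild type replicate 1 or 2 alone the bound was 151-fold or 72.2-fold for nrn1lb, 144-fold or 78.4-fold for impg2b and 120.3-fold or 92.9-fold for jac1. GNB3, a cone transducin subunit, fell from 220.2 ± 23.5 to 0.254 ± 0.157 CPM (log2 fold change -9.73, and -10.50 without knockout replicate 1). The cone opsins OPN1SW and opn1lw2 fell from 29.9 ± 4.41 to 0.126 ± 0.02402 CPM and from 102 ± 16.7 to 0.722 ± 0.145 CPM. The opsin opn1mw1, lactbl1a and SNX19 (ENSDARG00000061101) each had 2 counts over the knockout libraries, all in replicate 1 for opn1mw1 and lactbl1a and in replicate 2 for SNX19. Their wild-type to knockout ratios were 207 (95% counting interval 56.4 to 1726), 366 (100.2 to 3034) and 129 (34.6 to 1077). The largest decreases also included emilin3a, from 63.4 ± 4.37 to 0.289 ± 0.0987 CPM, and the mitochondrial creatine kinase CKMT2 (ENSDARG00000069615), from 63.8 ± 4.704 to 0.361 ± 0.0467 CPM.

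Among the genes that rose most, RRM2 (ENSDARG00000078069), a ribonucleotide reductase subunit, went from 2.56 ± 0.931 to 158 ± 2.09 CPM. By contrast, the other gene with that symbol (ENSDARG00000020711) had a log2 fold change of -0.11 (adjusted p = 0.6098). LIN28A, an RNA-binding protein of early embryonic cells, rose at both of its genes, from 5.17 ± 0.816 to 182 ± 5.91 CPM at ENSDARG00000016999 and from 0.342 ± 0.008697 to 7.78 ± 0.453 CPM at ENSDARG00000004328. SALL4, a transcription factor of embryonic progenitors, rose from 14.6 ± 2.25 to 211 ± 0.587 CPM, and the embryonic globin hbbe3 rose from 13.4 ± 2.62 to 399 ± 3.72 CPM. The actin gene actc1c rose from 0.336 ± 0.475 to 21.4 ± 3.06 CPM, with all 6 of its wild-type counts in replicate 2, without which wild type had no count. Without replicate 1 its log2 fold change was 4.999, against 6.14 with both. PRTG rose from 1.21 ± 0.976 to 26.7 ± 2.102 CPM, ftr43 from 0.497 ± 0.0881 to 17.1 ± 0.225 CPM, olfm4.1 from 0.441 ± 0.00891 to 7.57 ± 0.291 CPM, bcl3 from 0.535 ± 0.5101 to 7.29 ± 0.217 CPM and DCTPP1 from 0.298 ± 0.0528 to 5.04 ± 0.322 CPM. Without wild type replicate 1 or 2 the log2 fold change was 3.83 or 5.66 for PRTG, against 4.54 with both, and 3.03 or 5.35 for bcl3, against 3.86. The cytokine gene il11b had 3 wild-type counts, and its knockout to wild-type ratio was 30.04 (counting interval 10.16 to 147). Its log2 fold change was 4.84, and 5.58 without wild type replicate 2.

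Of 20239 genes tested, 4608 rose and 4946 fell in the knockout at adjusted p under 0.05 (edgeR), 47.2% of the genes tested. At least 2-fold changes numbered 2132 increases and 3451 decreases, and at least 8-fold changes 152 and 527. In 77.03% of genes the groups did not overlap. Chance gives 33.3% if the 4 libraries are exchangeable. The knockout pair was much closer than the wild-type pair, so chance separation is more frequent here and 33.3% is too low a reference. The first principal component held 84.7% of the variance and separated the genotypes, and the second held 12.7% and separated the wild-type libraries. The biological coefficient of variation was 21.9% in wild type and 4.37% in the knockout. Across 20239 genes, gene length had a Spearman correlation of 0.243 with the difference of wild type replicate 2 from replicate 1. It was 0.0866 for the knockout pair and 0.0196 for the fold change. Thinned to one depth, the knockout pair differed beyond the 5% chance level in 10.7% of genes and the wild-type pair in 40.4%. The 5% level assumes independent reads, and no repeat of 1 library was compared. The excess therefore does not show that the libraries of a pair are separate biological samples. The heat-shock list took 4.77% and 4.502% of counts in wild type and 11.2% and 11.2% in the knockout. Mitochondrially encoded transcripts took 2.71% and 2.395% against 1.304% and 1.23%, so both shares followed genotype, as did every group difference described here. The labels do not say that replicates came from separate clutches, so the spread between libraries may be technical. The edgeR p-values of genes rest on that spread, pooled over the genotypes, and on a prior drawn from all genes. The camera p-values at a preset correlation rest on the spread across genes instead. The count of changed genes was 4779 without knockout replicate 1 and 4519 without knockout replicate 2, and the number of increases was 7028 without wild type replicate 2.

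BMP receptors, SMADs and target genes were more often higher than lower in the knockout. In the list of BMP SMADs and target genes, 18 of 29 genes rose and 4 fell (19 and 4 adjusted over the list alone), with a median log2 fold change of 0.98 (camera adjusted p = 5.60e-05, adjusted p = 0.271 with an estimated correlation). ID1, a direct target of BMP signalling, rose from 221 ± 22.96 to 569 ± 10.4 CPM (log2 fold change 1.37 ± 0.11 (SE)). The inhibitory SMAD gene SMAD6 (ENSDARG00000031763) rose from 12.6 ± 0.847 to 37.8 ± 0.897 CPM, the receptor-activated SMAD5 from 36.5 ± 4.05 to 95.8 ± 0.816 CPM and ZNF703 from 84.9 ± 3.46 to 189.6 ± 3.69 CPM. Among BMP ligands and receptors, 17 of 30 genes rose and 3 fell (17 and 3 adjusted over the list alone), with a median of 0.71 (camera adjusted p = 0.0108, adjusted p = 0.386 with an estimated correlation). BMP2 (ENSDARG00000041430) rose from 4.48 ± 0.315 to 17.9 ± 1.83 CPM (log2 fold change 1.99 ± 0.18 (SE)), and the type I receptor genes bmpr1ba and BMPR1A (ENSDARG00000105045, ENSDARG00000019728) had log2 fold changes of 1.65 ± 0.14, 1.44 ± 0.13 and 0.96 ± 0.09 (SE). The other BMP2 gene (ENSDARG00000013409) was not called (log2 fold change -0.0055). The 3 genes that fell were GDF10 (ENSDARG00000073891), gdf3 and BMP1 (ENSDARG00000028053), with log2 fold changes of -3.20, -2.41 and -1.71. The other genes with the symbols GDF10 and BMP1 rose (0.72 and 0.46). BMP1 encodes a protease rather than a ligand or receptor, although its genes are counted in this list. The ligand and receptor list missed the threshold on TPM (adjusted p = 0.0503 by limma and camera).

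Antagonists and modulators of BMP were not called as a group by camera, and single members changed in both directions. In this list 9 of 22 genes rose and 3 fell (9 and 3 adjusted over the list alone). Its median was 0.14 (camera adjusted p = 0.1602, adjusted p = 0.411 with an estimated correlation). Follistatin, FST (ENSDARG00000052846), rose from 34.1 ± 0.949 to 102 ± 1.74 CPM and rgmd from 29.1 ± 4.19 to 108 ± 4.72 CPM. By contrast, the BMP antagonist GREM1 (ENSDARG00000029546) fell from 9.67 ± 3.07 to 0.996 ± 0.293 CPM (log2 fold change -3.28 ± 0.35 (SE)), whereas the other GREM1 gene (ENSDARG00000104618) rose (log2 fold change 2.37, adjusted p = 0.00966). FSTL1 (ENSDARG00000015559) rose from 6.89 ± 1.203 to 15.5 ± 0.599 CPM. By fry, which asks whether a list's own genes move on balance one way, the antagonist list was up (adjusted p = 0.0238).

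**Figure D1:**
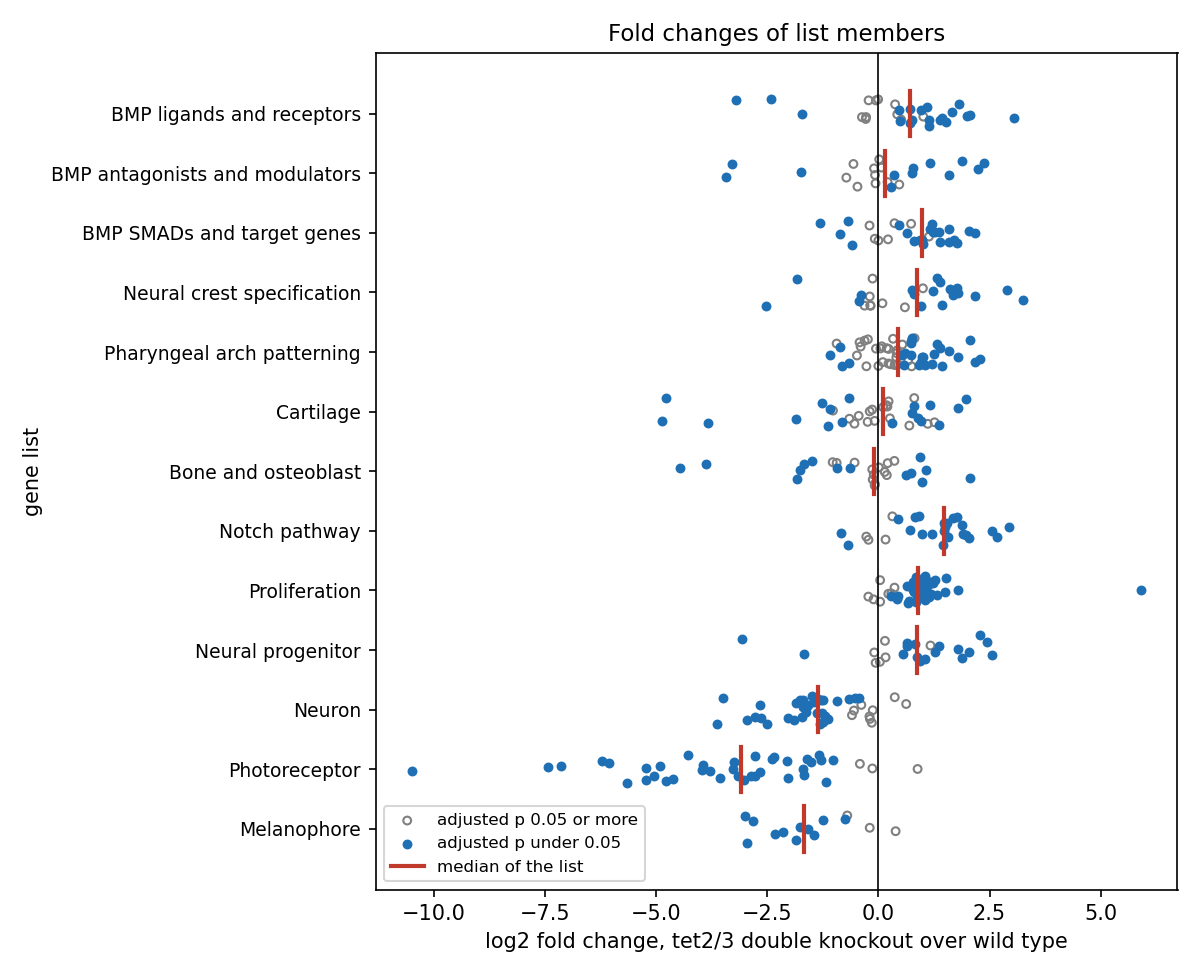
Log2 fold changes (knockout over wild type, x axis) of every tested member of 13 gene lists (y axis), with filled points for genes at adjusted p under 0.05, open points for the others and a red bar at the list median; genes with no knockout count are drawn at their bound. The Photoreceptor median lies at -3.09 and the BMP SMADs and target genes median at 0.98, and members of Cartilage and of Bone and osteoblast lie on both sides of 0.

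Genes of neural crest specification and pharyngeal arch patterning were more often higher than lower in the knockout. The skeletal matrix genes acana, COL10A1 (ENSDARG00000054753) and MATN1 were 29.2-fold, 22.2-fold and 14.2-fold lower. Camera called neither the Cartilage nor the Bone and osteoblast list, whose members changed in both directions. In Neural crest specification 14 of 26 genes rose and 4 fell (16 and 4 adjusted over the list alone). Its median was 0.87 (camera adjusted p = 0.00678, adjusted p = 0.386 with an estimated correlation). FOXD3, an early crest transcription factor, rose from 21.4 ± 0.402 to 55.7 ± 2.73 CPM, PRRX1 (ENSDARG00000033971) from 11.5 ± 0.111 to 35.04 ± 0.389 CPM and SOX8 (ENSDARG00000037782) from 0.5098 ± 0.229 to 4.76 ± 0.0327 CPM. The other SOX8 gene (ENSDARG00000105301) fell (log2 fold change -2.53, adjusted p = 0.00273). By contrast, TFAP2C fell from 98.05 ± 0.467 to 27.5 ± 0.0471 CPM. TFAP2A and TFAP2E were also called lower (log2 fold changes -0.43 and -0.39). Among the crest genes that were not called were SOX10 and crestin (-0.20 and -0.18). In Pharyngeal arch patterning 22 of 53 genes rose and 4 fell (22 and 4 adjusted over the list alone). Its median was 0.44 (camera adjusted p = 0.00387, adjusted p = 0.386 with an estimated correlation). The nuclear receptor gene nr2f5 rose from 27.5 ± 1.898 to 94.4 ± 2.79 CPM, pou3f3a from 77.6 ± 6.48 to 179 ± 5.68 CPM and msx2b from 1.98 ± 0.212 to 8.85 ± 0.761 CPM. By contrast, MEF2C (ENSDARG00000009418) fell from 41.2 ± 3.14 to 23.4 ± 0.04602 CPM, a call lost on TPM (adjusted p = 0.384) and without knockout replicate 1 (0.0646) or 2 (0.0639). Without wild type replicate 2 the arch list missed the threshold (adjusted p = 0.0601).

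In Cartilage 9 of 35 genes rose and 9 fell (10 and 9 adjusted over the list alone), and the list was not called (camera adjusted p = 0.704, adjusted p = 0.724 with an estimated correlation); its median was 0.11, its mean -0.25 and its test pointed down. The aggrecan gene acana fell from 26.1 ± 2.34 to 0.889 ± 0.446 CPM (log2 fold change -4.87 ± 0.32 (SE), and -5.48 without knockout replicate 1), matrilin MATN1 from 4.96 ± 0.368 to 0.343 ± 0.0725 CPM and COL9A1 (ENSDARG00000073699) from 31.2 ± 0.1496 to 8.59 ± 0.438 CPM. By contrast, col9a1b rose from 18.6 ± 1.14 to 47.6 ± 2.22 CPM. The COL2A1 genes had log2 fold changes of 0.31 (ENSDARG00000069093, called) and -0.14 (ENSDARG00000011407, not called). In Bone and osteoblast 6 of 27 genes rose and 8 fell (6 and 8 adjusted over the list alone). Its median was -0.10 (camera adjusted p = 0.293, adjusted p = 0.657 with an estimated correlation). COL10A1 (ENSDARG00000054753), a collagen of hypertrophic cartilage and of osteoblasts in fish, fell from 44.3 ± 1.33 to 1.99 ± 0.229 CPM (log2 fold change -4.47 ± 0.16 (SE)). The collagenase mmp13a fell from 6.14 ± 2.03 to 0.415 ± 0.0716 CPM and periostin, POSTN (ENSDARG00000043806), from 14.5 ± 1.46 to 5.15 ± 0.3204 CPM. By contrast, SP1 rose from 12.1 ± 1.11 to 23.3 ± 0.814 CPM (log2 fold change 0.94, and 0.92 without knockout replicate 2, where the call was lost). SP1 encodes a broadly expressed transcription factor and is not specific to bone. The other genes called higher in this list were runx2b, tnfrsf11b, SP7, ALPL and MMP14 (ENSDARG00000008388). Their log2 fold changes were 2.05, 1.08, 0.99, 0.72 and 0.63. The type I collagen genes COL1A1, COL1A2 and col1a1a were not called (log2 fold changes -0.10, -0.14 and -0.08). By fry both lists were down (adjusted p = 0.0238 and adjusted p = 0.0467).

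**Figure D2:**
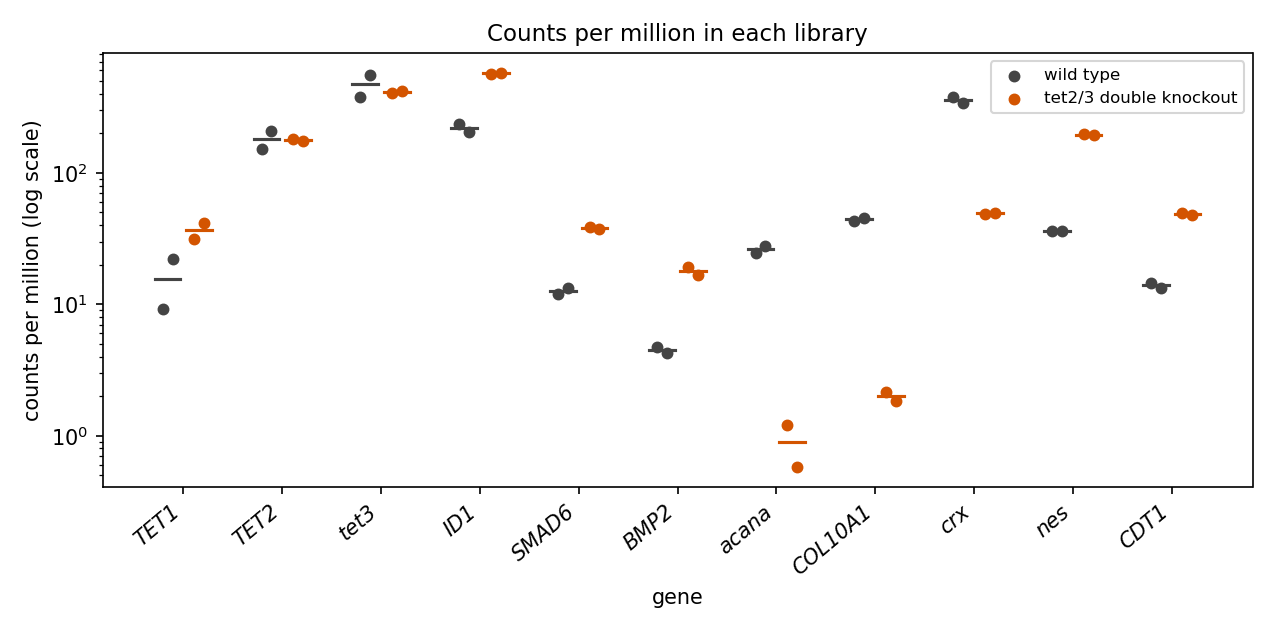
CPM in each library (log-scaled y axis) for each gene on the x axis, with a point per library and a bar at the group mean of n = 2. TET2 and tet3 overlap between genotypes. ID1, SMAD6, BMP2 (ENSDARG00000041430), nes and CDT1 lie higher in both knockout libraries, and acana, COL10A1 and crx lie lower in both.

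Photoreceptor and neuronal transcripts were lower in the knockout. In Photoreceptor 0 of 40 genes rose and 37 fell (0 and 37 adjusted over the list alone), with a median of -3.09, also with the 2 members without a knockout count at their bounds (camera adjusted p = 1.05e-32, adjusted p = 0.271 with an estimated correlation). The photoreceptor transcription factor crx fell from 360.0 ± 28.4 to 49.1 ± 0.933 CPM and retinoschisin, rs1a, from 95.4 ± 10.6 to 2.53 ± 0.276 CPM. In Neuron 0 of 41 genes rose and 32 fell (0 and 32 adjusted over the list alone). Its median was -1.35 (camera adjusted p = 3.45e-18, adjusted p = 0.271 with an estimated correlation). The synaptic genes SNAP25 (ENSDARG00000058117), SYN2 and SYT1 fell from 171 ± 17.2 to 27.3 ± 0.381 CPM, from 136 ± 11.9 to 24.1 ± 0.165 CPM and from 431 ± 15.4 to 105 ± 0.174 CPM. In Retinal progenitor and inner retina 8 of 36 genes rose and 17 fell (8 and 18 adjusted over the list alone). Its median was -0.43 (camera adjusted p = 0.0346, adjusted p = 0.563 with an estimated correlation). On TPM this list missed the threshold (adjusted p = 0.0569 by limma and camera). VSX1 and rlbp1a fell from 201 ± 27.7 to 41.9 ± 3.91 CPM and from 35.3 ± 5.79 to 2.53 ± 0.0713 CPM. Lens was not called (9 of 30 rose and 2 fell, 7 and 1 adjusted over the list alone, camera adjusted p = 0.157, adjusted p = 0.758 with an estimated correlation). In it crybb1l2 rose from 47.1 ± 8.15 to 104 ± 10.4 CPM and LIM2 (ENSDARG00000041295) fell from 1.68 ± 0.159 to 0.253 ± 0.003101 CPM, whereas the other LIM2 gene (ENSDARG00000015445) rose (log2 fold change 0.99, adjusted p = 0.0241). Without wild type replicate 1 the Lens list was called (adjusted p = 0.00879). Glia and myelin was not called (6 of 22 rose and 10 fell, 7 and 11 adjusted over the list alone, camera adjusted p = 0.321, adjusted p = 0.674 with an estimated correlation). In it GFAP rose from 45.3 ± 2.704 to 122 ± 2.16 CPM. By contrast, olig1 had 2 knockout counts and a wild-type to knockout ratio of 98.8 (counting interval 26.4 to 832).

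Genes of dividing cells, neural progenitors and the Notch, Hedgehog, TGF-beta, Wnt and FGF pathways were more often higher than lower in the knockout. In Proliferation 36 of 43 genes rose and 0 fell (36 and 0 adjusted over the list alone). Its median was 0.88 (camera adjusted p = 6.72e-13, adjusted p = 0.386 with an estimated correlation). Among them were CDT1, from 13.97 ± 0.919 to 48.8 ± 1.24 CPM, CDC6, from 18.6 ± 0.856 to 52.4 ± 1.07 CPM, and CCND1, from 177 ± 0.7699 to 400.1 ± 12.9 CPM. In Neural progenitor 15 of 23 genes rose and 2 fell (16 and 2 adjusted over the list alone). Its median was 0.87 (camera adjusted p = 1.88e-06, adjusted p = 0.271 with an estimated correlation). Nestin, nes, rose from 35.9 ± 0.133 to 195 ± 3.62 CPM, the proneural gene neurog1 from 35.1 ± 0.571 to 130.2 ± 0.655 CPM and INSM1 (ENSDARG00000053301) from 122 ± 6.58 to 423 ± 10.3 CPM. NEUROD6 (ENSDARG00000040008), a gene of differentiating neurons, fell from 33.3 ± 1.37 to 3.96 ± 0.841 CPM. In Notch pathway 21 of 27 genes rose and 2 fell (21 and 2 adjusted over the list alone). Its median was 1.47 (camera adjusted p = 3.18e-12, adjusted p = 0.271 with an estimated correlation). The Notch targets her4.2 and her12 rose from 8.75 ± 0.926 to 55.4 ± 0.269 CPM and from 8.19 ± 1.46 to 63.6 ± 0.7296 CPM, and the ligand genes dlb and jag2b from 123 ± 9.505 to 457 ± 3.91 CPM and from 51.7 ± 1.18 to 151 ± 4.97 CPM. In Hedgehog pathway 11 of 16 genes rose and 1 fell (11 and 1 adjusted over the list alone). Its median was 1.204 (camera adjusted p = 2.58e-05, adjusted p = 0.386 with an estimated correlation). The transducer gene SMO rose from 43.2 ± 0.999 to 156 ± 4.86 CPM and the coreceptor gene BOC from 80.8 ± 1.47 to 249 ± 0.0389 CPM. In TGF-beta and activin pathway 12 of 24 genes rose and 1 fell (12 and 1 adjusted over the list alone). Its median was 0.76 (camera adjusted p = 4.15e-04, adjusted p = 0.386 with an estimated correlation). SMAD3 (ENSDARG00000010207) rose from 13.1 ± 1.42 to 72.7 ± 2.59 CPM and INHBB (ENSDARG00000040777) from 14.2 ± 1.41 to 64.2 ± 1.82 CPM. In Wnt and FGF target genes 17 of 29 genes rose and 2 fell (18 and 3 adjusted over the list alone). Its median was 0.69 (camera adjusted p = 8.49e-04, adjusted p = 0.292 with an estimated correlation). The FGF targets etv5b and DUSP6 rose from 116 ± 5.48 to 375 ± 4.72 CPM and from 151 ± 7.03 to 454 ± 2.92 CPM.

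Genes of the DNA methylation machinery also differed. In this list 14 of 26 genes rose and 3 fell (14 and 3 adjusted over the list alone). Its median was 0.55 (camera adjusted p = 0.0265, adjusted p = 0.386 with an estimated correlation). The maintenance methyltransferase DNMT1 rose from 93.00 ± 6.98 to 175 ± 4.61 CPM and dnmt3ba from 134 ± 10.9 to 253 ± 2.69 CPM. By contrast, DNMT3A (ENSDARG00000015566) fell from 105 ± 5.48 to 52.5 ± 3.42 CPM and zbtb4, which binds methylated DNA, from 21.2 ± 0.991 to 5.23 ± 0.499 CPM. None of the 3 TET enzymes passed the threshold by edgeR with the chosen settings, although TET1 passed with others, and adjusted over the list alone 0 passed. At unadjusted p under 0.05 the count was 1 (TET1), DESeq2 called 1 and limma on TPM 0. As the list had fewer than 5 members, it was not tested by camera. Germline and methylation-silenced genes were not called (1 of 10 rose and 1 fell, 1 and 1 adjusted over the list alone, camera adjusted p = 0.9498, adjusted p = 0.955 with an estimated correlation). Their median was -0.17, their mean -0.18 and their test pointed up. In this list ddx43 rose from 1.57 ± 0.483 to 5.26 ± 0.346 CPM and SYCP3 fell from 1.29 ± 0.395 to 0.325 ± 0.00399 CPM. The SYCP3 call was lost with DESeq2 (adjusted p = 0.0995) and without wild type replicate 1 (0.0509), knockout replicate 1 (0.129) or knockout replicate 2 (0.137).

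Melanophore genes were lower and xanthophore genes more often higher in the knockout. In Melanophore 0 of 14 genes rose and 11 fell (0 and 11 adjusted over the list alone). Its median was -1.67 (camera adjusted p = 4.47e-09, adjusted p = 0.271 with an estimated correlation). The melanin synthesis and melanosome genes TYRP1 (ENSDARG00000056151), pmela, OCA2 and SLC24A5 fell from 214 ± 29.1 to 27.4 ± 1.69 CPM, from 304 ± 45.8 to 60.3 ± 6.57 CPM, from 22.1 ± 1.896 to 3.13 ± 0.192 CPM and from 11.6 ± 0.592 to 1.45 ± 0.0177 CPM. In Xanthophore 7 of 11 genes rose and 0 fell (7 and 0 adjusted over the list alone). Its median was 1.103 (camera adjusted p = 3.66e-04, adjusted p = 0.386 with an estimated correlation). The pteridine gene gch2 rose from 85.4 ± 7.03 to 252 ± 0.536 CPM and aox5 from 25.7 ± 1.06 to 86.2 ± 1.76 CPM. Iridophore was not called (5 of 14 rose and 4 fell, 6 and 4 adjusted over the list alone, camera adjusted p = 0.527, adjusted p = 0.655 with an estimated correlation), and pnp4a fell from 36.2 ± 0.298 to 8.48 ± 0.2797 CPM. By fry Iridophore was up (adjusted p = 0.0244). The difference between the pigment lists was not tested.

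Erythroid genes were more often higher, and myeloid and lymphoid genes more often lower, in the knockout. In Erythroid 11 of 25 genes rose and 3 fell (12 and 3 adjusted over the list alone). Its median was 0.25 (camera adjusted p = 2.59e-04, adjusted p = 0.287 with an estimated correlation). The transcription factor gene klf17 rose from 6.42 ± 0.0985 to 38.4 ± 0.6804 CPM, blf from 7.696 ± 0.6703 to 41.2 ± 1.55 CPM and the heme enzyme UROD from 7.305 ± 1.22 to 30.3 ± 1.06 CPM. This list missed the threshold on TPM (adjusted p = 0.0539 by limma and camera). In Myeloid and lymphoid 3 of 26 genes rose and 16 fell (3 and 16 adjusted over the list alone). Its median was -1.095 (camera adjusted p = 1.94e-04, adjusted p = 0.386 with an estimated correlation). The macrophage gene MPEG1 (ENSDARG00000055290) fell from 9.98 ± 0.451 to 0.923 ± 0.139 CPM and il1b from 21.6 ± 0.7796 to 4.25 ± 0.229 CPM. Hematopoietic stem and progenitor cells was not called (7 of 20 rose and 6 fell, 8 and 6 adjusted over the list alone, camera adjusted p = 0.4896, adjusted p = 0.635 with an estimated correlation). Its median was 0.16 and its mean -0.03, and by fry it was up (adjusted p = 0.00190). GATA2 rose from 53.1 ± 2.92 to 185 ± 4.14 CPM and MYB from 16.4 ± 1.95 to 43.2 ± 1.49 CPM. By contrast, spi1a fell from 2.89 ± 0.0272 to 0.235 ± 0.0284 CPM. In Interferon response 9 of 15 genes rose and 2 fell (10 and 3 adjusted over the list alone). Its median was 1.11 (camera adjusted p = 0.00146, adjusted p = 0.313 with an estimated correlation). The transcription factor genes irf9 and irf1b rose from 4.35 ± 0.131 to 28.9 ± 1.38 CPM and from 29.1 ± 3.92 to 112 ± 2.29 CPM.

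Transcripts of skeletal muscle, epidermis and digestive organs were more often lower than higher in the knockout. In Skeletal muscle 2 of 40 genes rose and 28 fell (3 and 31 adjusted over the list alone). Its median was -0.76 (camera adjusted p = 1.08e-07, adjusted p = 0.386 with an estimated correlation). The myosin heavy chain genes myhz2 and smyhc2 fell from 328 ± 17.99 to 22.1 ± 0.0104 CPM and from 54.1 ± 6.895 to 2.37 ± 0.566 CPM. In Epidermis and ionocyte 1 of 38 genes rose and 23 fell (1 and 23 adjusted over the list alone). Its median was -0.72 (camera adjusted p = 2.29e-05, adjusted p = 0.526 with an estimated correlation). The keratin genes krt97 and krt91 fell from 55.1 ± 7.69 to 12.4 ± 0.3599 CPM and from 191 ± 26.4 to 66.5 ± 0.661 CPM. In Liver, pancreas and gut 5 of 45 genes rose and 28 fell (5 and 29 adjusted over the list alone). Its median was -1.37 (camera adjusted p = 6.38e-06, adjusted p = 0.386 with an estimated correlation). Transferrin, tfa, fell from 160.4 ± 13.2 to 25.1 ± 1.303 CPM and fibrinogen, fga, from 31.6 ± 3.605 to 7.45 ± 0.5004 CPM. By contrast, PTF1A, a regulator of the early pancreas, rose from 7.14 ± 1.23 to 30.3 ± 1.52 CPM. Lipid and yolk metabolism was not called (6 of 40 rose and 16 fell, 6 and 16 adjusted over the list alone, camera adjusted p = 0.157, adjusted p = 0.526 with an estimated correlation), and the liver gene fabp10a in it fell from 4.64 ± 1.19 to 0.127 ± 0.0783 CPM (log2 fold change -5.14, and -5.87 without knockout replicate 1). Heart (6 of 30 rose and 12 fell, 6 and 12 adjusted over the list alone, camera adjusted p = 0.605, adjusted p = 0.657 with an estimated correlation) and Endothelium (10 of 31 rose and 7 fell, 11 and 7 adjusted over the list alone, camera adjusted p = 0.232, adjusted p = 0.456 with an estimated correlation) were not called. By fry Heart and Lipid and yolk metabolism were down (adjusted p = 0.0347 and 0.0444). Titin, TTN (ENSDARG00000028213), fell from 511 ± 94.4 to 48.02 ± 22.9 CPM, NOTCH1 (ENSDARG00000103554) rose from 202 ± 26.5 to 829 ± 43.5 CPM and plvapb fell from 16.8 ± 0.488 to 3.92 ± 0.0286 CPM.

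In Fin and limb bud 9 of 22 genes rose and 4 fell (9 and 4 adjusted over the list alone). Its median was 0.28 (camera adjusted p = 0.0336, adjusted p = 0.386 with an estimated correlation). Its increases included SALL4 and SALL1 (ENSDARG00000075891), the latter from 2.36 ± 0.625 to 13.8 ± 0.2204 CPM. Its call was lost without wild type replicate 1 (adjusted p = 0.0927), wild type replicate 2 (0.07895) or knockout replicate 1 (0.0607). It was also lost without the filter (0.107), at mean CPM of at least 2 (0.0653) and on TPM (0.376). HOX genes (8 of 33 rose and 8 fell, 8 and 8 adjusted over the list alone, camera adjusted p = 0.9895, adjusted p = 0.995 with an estimated correlation) and Hatching gland, notochord and floor plate (8 of 18 rose and 6 fell, 9 and 6 adjusted over the list alone, camera adjusted p = 0.232, adjusted p = 0.526 with an estimated correlation) were not called. HOXB5 (ENSDARG00000013057) fell from 57.6 ± 11.4 to 17.3 ± 0.135 CPM, hoxb1b rose from 5.12 ± 1.38 to 15.15 ± 0.237 CPM, agr1 fell from 18.6 ± 0.111 to 6.24 ± 0.358 CPM and loxl5b rose from 0.255 ± 0.114 to 2.78 ± 0.0853 CPM.

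Heat-shock transcripts were more often higher than lower in the knockout. The near-identical genes hsp70.3, hsp70l and hsp70.1, whose reads may be split among them, rose. Levels were 10727 and 9967 CPM in wild type and 40261 and 41163 CPM in the knockout for hsp70.3, 6633 and 6306 CPM in wild type and 29403 and 29913 CPM in the knockout for hsp70l, and 3208 and 2920.2 CPM in wild type and 11340.5 and 11403 CPM in the knockout for hsp70.1. In this list 21 of 42 genes rose and 10 fell (23 and 14 adjusted over the list alone). Its median was 0.38 (camera adjusted p = 5.00e-06, adjusted p = 0.492 with an estimated correlation). HSPA8 (ENSDARG00000037403) rose from 8.63 ± 0.143 to 85.1 ± 0.594 CPM, ATF3 from 479 ± 34.4 to 2271 ± 76.02 CPM and BAG3 from 21.7 ± 0.314 to 71.9 ± 1.93 CPM. In p53 and apoptosis 12 of 30 genes rose and 6 fell (12 and 6 adjusted over the list alone). Its median was 0.44 (camera adjusted p = 0.0443, adjusted p = 0.526 with an estimated correlation). The p53 targets cdkn1a and mdm2 rose from 4.08 ± 0.722 to 19.2 ± 0.645 CPM and from 26.98 ± 0.485 to 68.4 ± 4.62 CPM, and PLK2 (ENSDARG00000019130) fell from 71.98 ± 3.66 to 26.05 ± 0.729 CPM. The p53 list missed the threshold without wild type replicate 2 (adjusted p = 0.281) or knockout replicate 1 (0.05205). It also missed it at mean CPM of at least 2 (0.125), on TPM (0.152) and with the replicate number as a block (0.0569). The same held after thinning to one depth (0.0757) and with the heat-shock list left out (0.0909).

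Mitochondrially encoded transcripts were lower in the knockout. In this list 0 of 13 genes rose and 11 fell (0 and 11 adjusted over the list alone). Its median was -0.87 (camera adjusted p = 3.66e-04, adjusted p = 0.386 with an estimated correlation). Cytochrome b, MT-CYB, fell from 1507 ± 178 to 779 ± 48.7 CPM. In Ribosomal proteins 30 of 74 genes rose and 1 fell (17 and 1 adjusted over the list alone). Its median was 0.49 (camera adjusted p = 6.52e-05, adjusted p = 0.657 with an estimated correlation). RPL15 rose from 579.9 ± 82.04 to 958 ± 51.4 CPM, a call lost without knockout replicate 2 (adjusted p = 0.0789). This list was not called by fry (adjusted p = 0.167). Circadian clock was not called (13 of 34 rose and 4 fell, 13 and 4 adjusted over the list alone, camera adjusted p = 0.1004, adjusted p = 0.635 with an estimated correlation). In it NR1D1 and PER2 rose from 2.09 ± 0.3698 to 18.7 ± 0.538 CPM and from 51.8 ± 2.93 to 185 ± 8.47 CPM, and cry3a fell from 517 ± 16.6 to 140.5 ± 0.0177 CPM. Without the low-count filter the clock list was called (adjusted p = 0.0438).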

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

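Thinning, the gene-length offsets and omission of the heat-shock list were chosen after the data were seen. The number of changed genes stayed within 1.5 times 9554 under each alternative other than those that leave out a library, from 6939 with limma on TPM to 10758 with the replicate block, and no called gene changed direction with a call under any of them. Of the calls, 67.97% were kept with limma on TPM and 76.7% with DESeq2. Increases outnumbered decreases with DESeq2 (4120 and 3487), without the filter (4855 and 4372) and without either wild-type library. With each library left out in turn the number of changed genes ran from 4519 to 13640, increases from 2101 to 7028 and decreases from 2418 to 6612. The lowest counts came without a knockout library, where the spread rests on the wild-type pair, and the highest without a wild-type library, where it rests on the closer knockout pair. In each such fit the lone sample is assumed to vary like the other genotype. Whether the replicate numbers pair the samples is not known, as the labels name no shared clutch. Across genes the deviations of same-numbered libraries correlated at 0.1704 and those of different-numbered libraries at -0.1704. With 2 libraries per genotype these are 1 value with opposite signs, so it cannot decide the question. The block raised the count of calls from 9554 to 10758. For tet3 the log2 fold change ran from -0.43 to 0.11 with a library left out. TET2 changed sign with RLE (2.22e-04), DESeq2 (0.0367), no filter (0.04698), limma on TPM (0.0379) and length offsets (0.0399). It ran from -0.22 without wild type replicate 1 to 0.24 without wild type replicate 2. The cause was not tested. With an estimated correlation the adjusted p was 0.271 for BMP SMADs and target genes and 0.386 for BMP ligands and receptors, Neural crest specification and Pharyngeal arch patterning. That test takes its p from the 2 residual degrees of freedom, and the one with a preset correlation does not, so the losses do not show correlated genes. BMP ligands and receptors had 0.0503 with limma on TPM. Fry called BMP antagonists and modulators and Cartilage (0.0238) and Bone and osteoblast (0.0467). It also called Hematopoietic stem and progenitor cells (0.00190), Iridophore (0.0244), Heart (0.0347) and Lipid and yolk metabolism (0.0444), which camera did not. With a library left out, the adjusted p of Pharyngeal arch patterning ran from 0.00314 to 0.0601. Lists that were not called changed direction, with these adjusted p values: Glia and myelin at mean CPM of at least 2 (0.926), HOX genes without wild type replicate 1 (0.973) and knockout replicate 2 (0.9900), and Germline and methylation-silenced genes with limma on TPM (0.886), fry (0.384) and without knockout replicate 1 (0.672) or 2 (0.888). Over all 4 left-out libraries, turned or not, they ran from 0.511 to 0.9900 and from 0.672 to 0.997. Over the other named genes and all alternatives, 2773 values kept direction and side of the threshold, 21 lost the call, 10 gained it, all for TET1, and none changed direction. Over the lists other than BMP and craniofacial, 489 values kept both, 39 lost the call and 6 gained it. With the block, p53 and apoptosis had 0.0569 and TET1 passed (log2 fold change 1.324, adjusted p = 3.29e-05). DESeq2 was not run for lists, and legacy=FALSE does not enter the list test and is not counted for lists. The shallowest library holds 8123036 counts, and calls at that depth fell to 7820.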

Other observations

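The 3 added lists, thinning, the gene-length offsets and omission of the heat-shock list were chosen after the main results were seen, and the comparison of BMP genes with other signalling lists after its values were seen. The added lists hold no gene of the fixed lists, and 2 genes whose values had been seen were removed. Genes that decline after the first day of development were more often higher than lower in the knockout: 37 of 59 rose and 5 fell (median 0.67, camera adjusted p = 7.78e-09, adjusted p = 0.167 with an estimated correlation). MYCN rose from 84.1 ± 3.53 to 283 ± 2.28 CPM, mych from 61.8 ± 8.24 to 292 ± 3.401 CPM and TRIM71, a let-7 target, from 106 ± 11.4 to 332 ± 4.35 CPM. Genes that increase in the larva were mostly lower: 2 of 85 rose and 58 fell (median -1.29, camera adjusted p = 2.81e-17, adjusted p = 0.05001 with an estimated correlation). The neuropeptide precursor vgf fell from 270.4 ± 0.1099 to 54.4 ± 0.152 CPM, scg2b from 351 ± 18.9 to 83.3 ± 0.3296 CPM and the glutamate receptor gene GRIA2 (ENSDARG00000052765) from 84.6 ± 3.49 to 14.3 ± 1.56 CPM. Many genes of the larval list are neuronal, as are genes of the Neuron list already seen to be lower, so it is not independent of that list in kind.

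By camera the Photoreceptor, Neuron and Melanophore lists were down and the Proliferation, Notch pathway and Neural progenitor lists up in the knockout, and Skeletal muscle, Liver, pancreas and gut, Epidermis and ionocyte and Myeloid and lymphoid were also down (adjusted p from 0.271 to 0.526 with an estimated correlation). Against a split of differentiated from progenitor cells, Erythroid and Xanthophore were up and Retinal progenitor and inner retina was down (adjusted p = 0.287, 0.386 and 0.563 with an estimated correlation). Heart, Endothelium, Lens, Cartilage, Bone and osteoblast and Hematopoietic stem and progenitor cells were not called by camera. Of these, fry had Heart, Cartilage and Bone and osteoblast down (adjusted p = 0.0347, 0.0238 and 0.0467). It had Hematopoietic stem and progenitor cells up (adjusted p = 0.00190) and did not call Endothelium (0.0662) or Lens (0.363). Library depth, which was higher in the knockout, is argued against. After thinning to one depth, 94.2% of 154 called members of the Photoreceptor, Neuron, Melanophore, Proliferation, Notch pathway and Neural progenitor lists kept call and direction. Coverage of long transcripts is argued against also, since 99.4% kept them with the length trend removed. A less advanced developmental stage of the knockout embryos is a candidate explanation. Of 102 called genes of the early and larval lists, 93.1% went in the direction it predicts. By list, 88.1% of the called early genes were higher, and 3.33% of the called larval genes were. As the lists were written after the main results were seen and many larval genes are neuronal, they do not test this explanation independently. Whether the genotype slows development or the embryos differed in clutch or staging stays open, as each genotype was collected at 1 labelled age with no morphological stage given, and fewer differentiated cells at an equal stage was not tested.

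Of 29 BMP SMADs and target genes, 18 rose and 4 fell in the knockout (adjusted p = 0.271 with an estimated correlation). Depth is argued against, since 90.9% of 22 called members kept call and direction after thinning. A rise shared with other signalling pathways may account for it: the mean log2 fold change was 0.76 for this list and 0.93 for the pooled Notch, Hedgehog, TGF-beta and activin, and Wnt and FGF lists, a difference of -0.17 (95% bootstrap interval -0.55 to 0.20, two-sided permutation p = 0.415 across genes, which are not independent replicates). The interval leaves room for a BMP-specific excess of up to its upper bound. A direct effect of TET loss on BMP genes stays open and was not tested, as no methylation data were analysed here.

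Of 42 heat-shock and unfolded protein response genes, 21 rose and 10 fell in the knockout. Under TMM their share of counts did not set the scale of other genes: with the list left out, 99.2% of 9523 other called genes kept call and direction. TMM trims genes of extreme ratio or level, so this outcome was largely set by the method. It does not test the assumption of TMM that most genes are unchanged. A general stress response to handling cannot be told apart from an effect of genotype: 66.7% of 39 called immediate early and stress genes were higher, between the bounds set for and against it (camera adjusted p = 0.00206, adjusted p = 0.301 with an estimated correlation). FOSL1 rose from 311 ± 8.32 to 950.2 ± 14.5 CPM, sgk1 from 74.4 ± 8.701 to 239 ± 2.27 CPM and KLF6 from 273 ± 4.64 to 647 ± 5.14 CPM, while NR4A1 fell from 570.0 ± 60.1 to 176 ± 4.75 CPM. Both knockout libraries shared the pattern, and the labels give no collection day.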
